A study of Mus musculus with 6 samples.

How the data were processed

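RNA was extracted with Trizol from frozen inguinal fat and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. Of the 6 libraries, 3 came from fat pads injected with a virus carrying the Hnrnpa2b1 coding sequence and 3 from pads given the control virus; groups were taken from the treatment given in the labels. The submitters' processing notes name Bowtie and the genome build mm10, with no version or role. The counting program, the annotation release, the filters and the strand setting are not given in the sources used here. The authors deposited 1 table of whole-number read counts per gene, not normalized, with a gene ID and symbol for each of 52550 genes and 1 column per library, per the file headers. No column of another sample was present (0).

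The low counts have an uneven distribution: the values 1, 2, 3 and 4 occur 8211, 6699, 7257 and 3493 times. The numbers were treated as raw counts, but they may be rounded estimates in which reads of overlapping genes were divided, so genes with overlapping exons are uncertain. Besides those marked beside their values, these are Csf1r, Cd247, Egfl7, Cdc20, Cebpa, Lipe, Hnrnpa3, Mogat2 and Irs1. The table also repeats 91 symbols under a further gene ID; for gene lists the ID with most counts was used. Alternative splicing, which the series' design also mentions, was not analysed here, because the table gives counts per gene only. Total counts per library of 72961324 to 86663359 set the precision of each value. Counting intervals and floors cover counting error only, since reads carry no molecular identifiers and are not independent molecules.

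Counts were analysed in R 4.3.3. Of the 31438 genes with any count, the 19146 kept by edgeR's filterByExpr with default settings (at least 10 counts in enough libraries and 15 in total) were tested; they held at least 99.91% of the counts of each library. TMM factors lay between 0.917 and 1.03. The main test was the quasi-likelihood F test of edgeR 4.0.16 (robust fit, group as the only term, two-sided), with Benjamini-Hochberg adjusted p under 0.05 called. The standard error of a log2 fold change was computed as its size divided by the square root of F, and the common dispersion corresponds to a biological coefficient of variation of 33.6%. CPM values use TMM-scaled library sizes. For named genes with fewer than 200 counts in a group, the ratio of summed counts was given an exact 95% (Clopper-Pearson) interval; where a group had 0 counts, a floor of 3 counts over the group was used. Gene coordinates were taken from GENCODE M21, on the mm10 assembly, by gene ID.

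The 40 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 40 lists; camera with an estimated correlation and fry were run beside it. Counts called adjusted over the list alone use Benjamini-Hochberg adjustment within the list. Fry tests whether the genes of a list move on balance in 1 direction, and its mixed test lets them move either way. Both leave out any comparison with other genes. Named were Hnrnpa2b1; the 10 higher and 10 lower genes with the largest log2 fold change among those past the threshold, with mean log2 CPM of at least 1, non-overlapping groups and a symbol that is not a placeholder; up to 4 called members of each called list, or else the 2 with the smallest p; and 12 genes of fat and of the hnRNP family, whatever their values. Had fewer than 5 genes passed in a direction, the smallest p-values would have filled up to 5, which was not needed. Other called members of the lists, and called imprinted genes, were named after their values were seen.

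The scripts were tested on simulated counts for 19146 genes with the means, dispersions and library sizes of this comparison, in which 200 genes were changed by known folds. At the threshold used, 0 of 50 genes changed 1.5-fold were recovered, 16 of 50 at 2-fold, 42 of 50 at 4-fold and 47 of 50 at 8-fold, and 13 of 118 calls were false. A list shifted by 0.3 was called, and with no gene changed 0 genes and 0 lists were called. The simulated genes were drawn independently, so these list results do not test camera's preset correlation where members move together. In the real data the estimated correlation was 0.706 for oxidative phosphorylation and 0.898 for B cell markers. Camera with an estimated correlation gave adjusted p = 0.593 to oxidative phosphorylation and also to triglyceride synthesis, where the estimate was -0.00583. That value therefore does not show which calls depend on members moving together. Alternatives were DESeq2 size factors, library totals, upper-quartile factors, DESeq2 1.42.0 (Wald test), limma-voom with sample quality weights, no filter, CPM of at least 1 in 3 libraries, an adjusted p of 0.1, and each library left out in turn. A fit of 2 against 2 libraries, without the libraries at the ends of the first principal component, was added after seeing the data. Title numbers are not shared between the groups, so no pairing was used.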

Results

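Gene expression was measured by RNA sequencing in inguinal white adipose tissue, the subcutaneous fat pad of the groin, of C57BL/6 mice. The pads of 1 group had been injected with an adeno-associated virus carrying the coding sequence of mouse Hnrnpa2b1, an RNA-binding protein of the hnRNP family that takes part in splicing and RNA transport. The other group had received a control virus, labelled as an adeno-associated virus expressing a scrambled control. Each group held 3 libraries, named here A2B1 1 to 3 and control 1 to 3. Total counts per library lay between 72961324 and 86663359, and 24909 to 26259 genes had at least 1 count. Mitochondrial transcripts took 11.7% to 14.4% of the counts, with the highest share in A2B1 library 1. The nearest pair of libraries, control 2 and control 3, still differed by 69.5 times the counting noise in a chi-square test over genes, so no library was a copy of another. On the first principal component, with 52.8% of the variance, A2B1 library 1 lay at -107.6, A2B1 library 3 at -50.6, A2B1 library 2 at 18.1 and the controls between 26.4 and 69.6. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical in part.

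The delivered gene was examined first, as a check of the labels. Hnrnpa2b1 (ENSMUSG00000004980, mm10 chromosome 6, 51460932 to 51469894, minus strand) had a normalized count of 766 ± 20.6 CPM (read count scaled to library size; SD, n = 3) in A2B1 libraries and 562 ± 40.1 (SD, n = 3) in controls. All 3 A2B1 libraries lay above all 3 controls, the nearest values being 748 and 605 CPM. The fitted ratio was 1.36 (95% interval 1.18 to 1.58), a log2 fold change of 0.45 (SE 0.09). Its adjusted p of 0.0654 in the edgeR test missed the threshold of 0.05, while DESeq2 gave an adjusted p of 0.000113 and limma-voom 0.0496; over all alternatives the adjusted p ranged from 0.000113 to 0.217. An exact two-sided permutation test of the CPM gave p = 0.1, the smallest that 3 against 3 libraries allow. Gene counts do not separate the viral coding sequence from the transcript of the mouse's own gene. The close paralogs Hnrnpa1 and Hnrnpa3 had log2 fold changes of -0.08 (SE 0.09, adjusted p = 0.614) and 0.13 (SE 0.10, adjusted p = 0.471), with overlapping groups.

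The main comparison asked which transcripts differ between fat pads given Hnrnpa2b1 and fat pads given the control virus. Genes of thermogenic fat, lipid synthesis and fatty acid oxidation were among the 95 genes that rose. Cidea, at 4.47-fold, led the 85 of them that passed the naming rule. Leptin, the extracellular matrix gene Sparc and a set of genes with almost no counts in the A2B1 libraries were among the 254 that fell. Together 349 of 19146 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and 4639 had an unadjusted p under 0.05. Of the 349, 179 differed at least 2-fold, 23 of them higher and 156 lower. All 349 had non-overlapping groups, as had 30.6% of all tested genes. The average over all splits of 6 libraries into 3 and 3 is 10%. Genes move together, so the share in any 1 split can lie far from that average, and it was not computed for the other splits. Scaling by library totals alone called 49 genes higher and 251 lower, and DESeq2 called 1332 higher and 1587 lower. Leaving out A2B1 library 1, 2 or 3 left 11, 13 or 10 calls, and leaving out control library 1, 2 or 3 left 57, 19 or 40. All 349 genes kept their sign in each of these fits, which their non-overlapping groups made nearly certain in advance. Without both A2B1 library 1 and control library 1, a setting chosen after seeing the data, 7 genes were called. Of the 46 named genes that passed the threshold, 4 passed it in each of the 6 fits without 1 library: Unc79, Sfrp5, the Itgam readthrough model and the noncoding gene ENSMUSG00000111840, while 33 passed it in none of them. Under the other scalings, filters and tools 33 of the 46 kept their call in every fit and 13 lost it in at least 1. Plin5 was called in 3 of the 7 fits, Cidec and Apln in 4, and Cpt1b, Acacb and Itgad in 5. The other 7, each called in 6, were Slc5a7, Srebf1, Hadhb, Col4a2, Adig, Nrg4 and Vegfa.

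**Figure D1:**
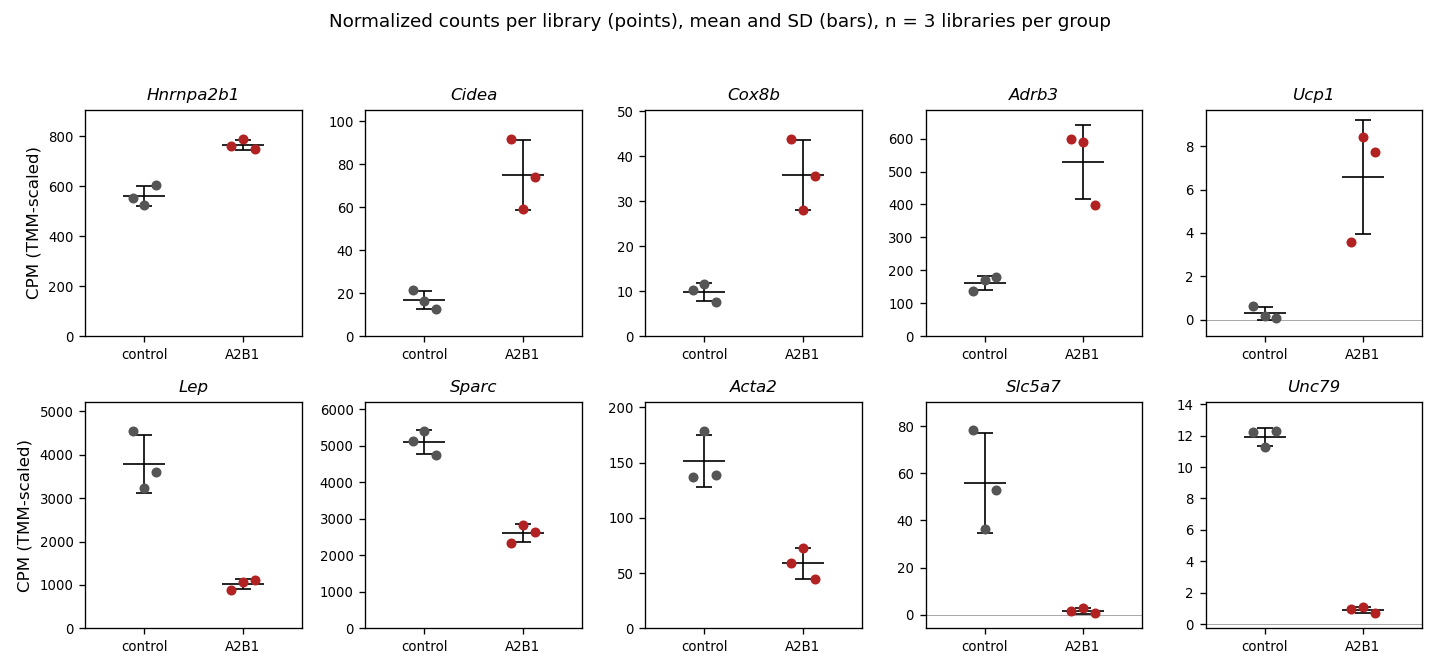
Read counts scaled to library size (CPM with TMM factors, linear axes) of 10 named genes in each of the 3 control (grey) and 3 A2B1 (red) libraries, with the mean (long bar) and SD (capped bar) of each group. In each panel the A2B1 points lie on 1 side of the control points, from 766 against 562 CPM for Hnrnpa2b1 to 1018 against 3792 CPM for Lep; Hnrnpa2b1 and Ucp1 did not pass the adjusted threshold in the main edgeR test but did in DESeq2 and limma-voom.

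Thermogenic genes held several of the largest increases under the naming rule. Cidea, a lipid droplet protein abundant in brown and beige adipocytes, rose from 16.8 ± 4.37 to 75.0 ± 16.2 CPM (SD, n = 3 each), a log2 fold change of 2.16 (SE 0.24, adjusted p = 0.0248). Cox8b, a cytochrome c oxidase subunit of brown fat and muscle, rose by 1.86 (SE 0.22, adjusted p = 0.0251), Plin5, which coats lipid droplets in oxidative tissues, by 1.70 (SE 0.29), and Cpt1b, the muscle-type importer of fatty acids into mitochondria, by 1.33 (SE 0.23). Plin5 and Cpt1b both stood at an adjusted p of 0.0497 and lost their calls in some of the 7 other fits, with adjusted p-values up to 0.0594 and 0.0541. The exons of Cpt1b overlap Gm44502 on the same strand, so its count is uncertain. Ucp1, the uncoupling protein of thermogenic fat, had 248, 670 and 575 counts in the A2B1 libraries and 49, 15 and 5 in controls, a ratio of 24.1 (95% counting interval 18.9 to 31.1), with an adjusted p of 0.0695 in edgeR, 5.14e-08 in DESeq2 and 0.0301 in limma-voom. The interval covers counting error only; the fitted log2 fold change was 4.50, or 5.83 without control library 1 and 4.01 without control library 3. Ppargc1a, a coactivator of mitochondrial biogenesis, had 30.2 ± 3.96 against 16.2 ± 4.12 CPM (SD, n = 3 each; log2 fold change 0.89, adjusted p = 0.0827). Of the 27 tested members of the brown and beige thermogenic list, 4 rose, 0 fell and 23 did not pass; adjusted over the list alone, 15 were higher. The list's median log2 fold change was 0.99, and camera with a preset correlation called it higher (adjusted p = 2.5e-07), with an adjusted p = 0.593 with an estimated correlation. The mature adipocyte list was not called (median 0.29, adjusted p = 0.113), with 2 of its 22 members higher and 2 lower.

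Adrb3, the beta-3 adrenergic receptor of adipocytes (chromosome 8, 27225776 to 27250616), rose from 162 ± 21.3 to 529 ± 113 CPM (SD, n = 3 each), a log2 fold change of 1.71 (SE 0.19, adjusted p = 0.0248). Its exons overlap those of Gm45470 on the other strand, and the strand setting of the counting is not given in the sources used here. The unconventional myosin Myo5c rose by 1.56 on the log2 scale (SE 0.17) and the imprinted gene Nap1l5 by 1.36 (SE 0.21). Also among the 10 largest increases under the naming rule were 2 long noncoding genes on chromosome 9, ENSMUSG00000111840 (85332352 to 85348065) at 2.13 (SE 0.13, adjusted p = 0.00841) and ENSMUSG00000111147 (61032212 to 61059116) at 1.71 (SE 0.22, adjusted p = 0.0293). The exons of the latter overlap Gm39348 on the other strand, so its count is as uncertain as that of Adrb3. Among 17 tested adrenergic and PKA target genes, 0 passed in the main edgeR test, 3 had an unadjusted p under 0.05, all higher, and DESeq2 called 3 (median 0.03, camera adjusted p = 0.373).

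The de novo lipogenesis list rose in part. Acacb and Acaca, the acetyl-CoA carboxylases that produce malonyl-CoA, rose by 1.58 (SE 0.26, adjusted p = 0.0467) and 1.17 (SE 0.19, adjusted p = 0.0432) on the log2 scale; Acacb lost its call in 2 of the 7 other fits (adjusted p up to 0.0511). Srebf1, a transcription factor of lipid synthesis, rose from 150.04 ± 15.6 to 256 ± 24.3 CPM (SD, n = 3 each; log2 fold change 0.77), and Aacs, which activates acetoacetate for lipid synthesis, rose by 0.63 (SE 0.09, adjusted p = 0.034). The count of Srebf1 is uncertain, since its exons overlap Mir6922 and, on the other strand, Rai1. Scd1, the desaturase that makes monounsaturated fatty acids, had 39726 ± 7234 against 19660 ± 5430 CPM (SD, n = 3 each) with an adjusted p of 0.0906, and the fatty acid synthase Fasn 2237 ± 752 against 1514 ± 413 with an adjusted p of 0.286. Of 22 tested genes of de novo lipogenesis 4 rose and 18 did not pass, and 10 were higher and 1 lower adjusted over the list alone. The list had a median of 0.49 and was called higher by camera (adjusted p = 0.000362), with an adjusted p = 0.593 with an estimated correlation. Without A2B1 library 1 its median was 0.31.

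In fatty acid oxidation, Acadvl and Hadhb, which carry out steps of long-chain beta-oxidation, rose with Cpt1b, Acadvl by 0.67 (SE 0.10, adjusted p = 0.0374) and Hadhb by 0.52 (SE 0.09, adjusted p = 0.0453). The exons of Acadvl overlap Dvl2 on the other strand, so its count is uncertain. Cpt1a, the liver-type counterpart of Cpt1b, fell by 0.88 on the log2 scale (SE 0.14, adjusted p = 0.0402). In all, 3 of 25 members rose, 1 fell and 21 did not pass, with 16 higher and 1 lower adjusted over the list alone. Its median was 0.29 and its camera adjusted p 5.06e-07, with an adjusted p = 0.593 with an estimated correlation. Oxidative phosphorylation had positive values in 74 of 76 subunits, of which 38 had an unadjusted p under 0.05. Of the 76, 0 passed over all genes in the main edgeR test, 18 did in DESeq2 and 3 in limma-voom, and 8 passed adjusted over the list alone (median 0.30, camera adjusted p = 4.42e-11, and an adjusted p = 0.593 with an estimated correlation). Its smallest p-values belonged to the ATP synthase subunit Atp5c1 at 0.53 (SE 0.10, adjusted p = 0.0589) and the complex I subunit Ndufb10 at 0.49 (SE 0.09, adjusted p = 0.0618), which both passed in 3 of 7 other fits, 1 of them edgeR with the CPM filter. The citrate cycle list showed 17 of 18 positive members, 11 with an unadjusted p under 0.05. Over all genes 0 passed in the main edgeR test, 8 in DESeq2 and 1 in limma-voom, and 9 passed adjusted over the list alone (median 0.32, camera adjusted p = 1.04e-05, and an adjusted p = 0.593 with an estimated correlation). There, Idh3a had 540 ± 18.7 against 398 ± 25.9 CPM (SD, n = 3 each; adjusted p = 0.064) and Dld a log2 fold change of 0.34 (adjusted p = 0.108).

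Lists of splicing factors related to the delivered protein shifted by little. Among 17 SR splicing factor genes, 15 had positive values and 10 an unadjusted p under 0.05. Over all genes 0 passed in the main edgeR test or limma-voom and 7 in DESeq2, and 7 were higher adjusted over the list alone; the median was 0.26 and camera called the list higher (adjusted p = 0.000274, and an adjusted p = 0.593 with an estimated correlation). Tra2b had a log2 fold change of 0.32 (SE 0.08, adjusted p = 0.0904) and Srsf11 0.36 (SE 0.09, adjusted p = 0.0928). The hnRNP family without Hnrnpa2b1 held 22 positive members of 26, 5 of them with an unadjusted p under 0.05. In that family 0 passed over all genes in the main edgeR test or limma-voom, 3 in DESeq2 and 0 adjusted over the list alone (median 0.14, camera adjusted p = 0.0131, and an adjusted p = 0.593 with an estimated correlation). Its smallest p-values belonged to Syncrip at 0.31 (SE 0.08, adjusted p = 0.103) and Hnrnph3 at 0.38 (SE 0.11, adjusted p = 0.133), both of uncertain count because their exons overlap Gm20537 and Rufy2. Without A2B1 library 2 the hnRNP list was no longer called even with the preset one (median 0.11, adjusted p = 0.104), nor was it with library totals only (median 0.10, adjusted p = 0.0527). The core spliceosome, m6A and microRNA processing lists were not called (adjusted p = 0.529, 0.0873 and 0.529). Camera did call the m6A list higher with no filter (adjusted p = 0.0161), limma-voom (0.0464) and without A2B1 library 1 (0.0357), and with 2 against 2 libraries.

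Leptin, the adipocyte hormone that signals fat stores, fell while several other adipocyte genes did not pass the test. Lep (chromosome 6, 29060220 to 29073877) had 3792 ± 672 CPM in controls and 1018 ± 118 in A2B1 libraries (SD, n = 3 each), a log2 fold change of -1.90 (SE 0.17, adjusted p = 0.0166). Adiponectin, Adipoq, had 3506 ± 392 against 2777 ± 95.1 CPM (SD, n = 3 each), a log2 fold change of -0.34 with an adjusted p of 0.161. The adipogenic regulators Pparg and Cebpa had log2 fold changes of 0.66 (adjusted p = 0.181) and 0.33 (adjusted p = 0.425), and the lipases Pnpla2 and Lipe 0.39 (adjusted p = 0.169) and 0.15 (adjusted p = 0.632). Leaving out 1 library moved Pparg between 0.40 and 0.90 and Cebpa between 0.12 and 0.47. Pnpla2 moved between 0.28 and 0.47 and Lipe between 0.01 and 0.28.

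The 10 largest decreases under the naming rule were of genes with counts in every control library and at most 2.98 CPM in any A2B1 library. Pvalb, the calcium-binding protein parvalbumin, had 0 counts in all 3 A2B1 libraries and 215, 195 and 659 in controls, at least 320.1-fold lower against a floor of 3 counts over the group (adjusted p = 0.0402); the exact 95% counting interval begins at 259.9. Control library 3 held 659 of the 1069 control counts, and without it the fitted log2 fold change went from -11.40 to -10.61 (adjusted p = 0.0535). A gene model with the symbol Itgam (ENSMUSG00000108596, chromosome 7, 128062683 to 128128160) had 3, 1 and 1 counts against 1005, 914 and 1017, a control to A2B1 ratio of 528 (95% counting interval 226 to 1626; adjusted p = 0.006). It is named Gm49368 in GENCODE M21 and shares exons with the Itgam gene proper (ENSMUSG00000030786), which had 990, 2052 and 602 counts against 1376, 1571 and 1020, so the split of reads between them is uncertain. The neighbouring integrin gene Itgad (128154376 to 128223816) fell from 35.2 ± 16.1 to 0.549 ± 0.458 CPM (SD, n = 3 each; adjusted p = 0.0375); its exons overlap Gm17831 on the same strand and Cox6a2 on the other, so its count is uncertain. Slc5a7, the high-affinity choline transporter, fell from 55.9 ± 21.2 to 1.73 ± 1.19 CPM, and Lipf, a lipase best known from the stomach, from 19.6 ± 12.3 to 0.625 ± 0.125 (SD, n = 3 each). Unc79, a subunit of the NALCN sodium leak channel complex, fell from 11.9 ± 0.568 to 0.904 ± 0.207 CPM (SD, n = 3 each), a log2 fold change of -3.72 (SE 0.22, adjusted p = 0.00841). The glutamate receptor gene Grid1, the desmosomal plakophilin Pkp1, the clathrin uncoating factor Dnajc6 and the patched-domain gene Ptchd4 had log2 fold changes of -5.44, -5.20, -3.72 and -3.72. Counts of Grid1 and Unc79 are uncertain, since their exons overlap Gm27617 and Gm27976 on the same strand.

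Matrix, mural, fibroblast and endothelial lists were called lower by camera with the preset correlation, and 0 of them with an estimated one. Sparc, a matrix glycoprotein, fell from 5095 ± 326 to 2601 ± 244 CPM (SD, n = 3 each), a log2 fold change of -0.97 (SE 0.11, adjusted p = 0.0251). Tgfbi fell by 0.90 (SE 0.11, adjusted p = 0.0253) and the basement membrane collagen Col4a2, whose exons overlap Col4a1 on the other strand and whose count is therefore uncertain, by 0.72 (SE 0.12, adjusted p = 0.044). Of 33 collagen and matrix genes 3 fell, 0 rose and 30 did not pass, and 12 were lower adjusted over the list alone; the median was -0.52 and camera called the list lower (adjusted p = 5.06e-07, and an adjusted p = 0.593 with an estimated correlation). Without A2B1 library 3 its median was -0.30. Acta2, smooth muscle actin, fell from 151 ± 23.3 to 58.9 ± 14.2 CPM (SD, n = 3 each; adjusted p = 0.0375) and was the 1 call among 15 mural and smooth muscle markers, of which 7 were lower and 2 higher adjusted over the list alone (median -0.46, camera adjusted p = 0.0131, and an adjusted p = 0.593 with an estimated correlation). Fibroblast and progenitor markers had 0 calls of 20 in the main edgeR test, 4 in DESeq2 and 6 unadjusted p under 0.05, with 3 lower adjusted over the list alone (median -0.40, camera adjusted p = 0.00378, and an adjusted p = 0.593 with an estimated correlation); Dcn had a log2 fold change of -0.48 (adjusted p = 0.0827) and Mfap5 -0.67 (adjusted p = 0.0834). Endothelial markers had 0 calls of 20 in the main edgeR test, 4 in DESeq2 and 8 unadjusted p under 0.05, with 0 adjusted over the list alone (median -0.35, camera adjusted p = 0.00739, and an adjusted p = 0.609 with an estimated correlation); Egfl7 had a log2 fold change of -0.37 (adjusted p = 0.0935) and Erg -0.59 (adjusted p = 0.102). The mural and endothelial calls were lost without control library 2 (medians -0.25 and -0.10), the fibroblast call without A2B1 library 3 (median -0.29), and the mural call also without A2B1 library 1 (median -0.44).

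Skeletal muscle markers were called lower, with 17 of 20 members negative (median -1.93, also with Pvalb at its bound; camera adjusted p = 0.00378, and an adjusted p = 0.593 with an estimated correlation). Pvalb was the only member to pass over all genes, and 4 were lower adjusted over the list alone. Control library 3 lay 2.29 above the 6-library mean of the list on the log2 scale, and without that library the median was -0.64.

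Immune and proliferation lists were called lower with 0 members past the threshold over all genes in the main edgeR test. DESeq2 called 16 members of the B cell list, 6 of the macrophage list, 7 of the T and NK cell list and 14 of the cell cycle list, all lower; unadjusted p-values under 0.05 numbered 16, 6, 3 and 19. In limma-voom the B cell list had 1 call and the other lists 0. In the B cell list all 18 tested members were negative and 15 were lower adjusted over the list alone (median -4.18, camera adjusted p = 0.000163, and an adjusted p = 0.595 with an estimated correlation). Ighm, the IgM heavy chain, had 977 ± 323 against 377 ± 40.8 CPM (SD, n = 3 each; adjusted p = 0.051) and was called in 5 of 7 other fits, 3 of them edgeR with another scaling or filter. Fcer2a had 2651, 351 and 33 counts in the 3 controls and 19 to 25 in the A2B1 libraries (adjusted p = 0.152). Control library 1 lay 3.87 above the 6-library mean of this list and control library 2 1.22 above it, whereas control library 3 lay at -1.36, next to the A2B1 libraries at -1.17 to -1.32. Without control library 1 the median was -1.78. Lymph node stroma markers, which were not called (median -0.79, adjusted p = 0.265), were also highest in control library 1, at 1.68 above the mean. Their median was -0.48 without that library and -1.44 without control library 3, where they were called lower (adjusted p = 0.041). Macrophage markers were negative in 20 of 22 genes, with 0 passing adjusted over the list alone (median -0.71, camera adjusted p = 4.32e-05, and an adjusted p = 0.593 with an estimated correlation); Csf1r had 95.7 ± 16.9 against 49.96 ± 13.8 CPM (SD, n = 3 each; adjusted p = 0.0935) and Gpnmb 64.7 ± 22.2 against 25.9 ± 8.33 (adjusted p = 0.106). The macrophage median was -1.16 without A2B1 library 2 and -0.48 without A2B1 library 3. T and NK cell markers were negative in 19 of 23 genes, 0 passing adjusted over the list alone (median -1.75, camera adjusted p = 0.00558, and an adjusted p = 0.659 with an estimated correlation), with Cd247 at -1.06 (adjusted p = 0.0717) and Il7r at -2.41 (adjusted p = 0.161). Il7r had 22.7, 7.65 and 3.88 CPM in controls 1 to 3, and leaving out 1 library moved its value between -2.83 and -1.43. The T and NK cell call was lost without control library 1 (median -0.69) and without A2B1 library 1 (median -1.34). All 27 cell cycle genes were negative, 0 of them passing adjusted over the list alone (median -1.12, camera adjusted p = 1.1e-07, and an adjusted p = 0.593 with an estimated correlation); Ccnb1 had 681 counts in controls and 187 in A2B1 libraries (adjusted p = 0.0969) and Cdc20 568 and 172 (adjusted p = 0.0878). Control library 1 lay 1.20 above the mean of the cell cycle list, and without it the median was -0.63.

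**Figure D2:**
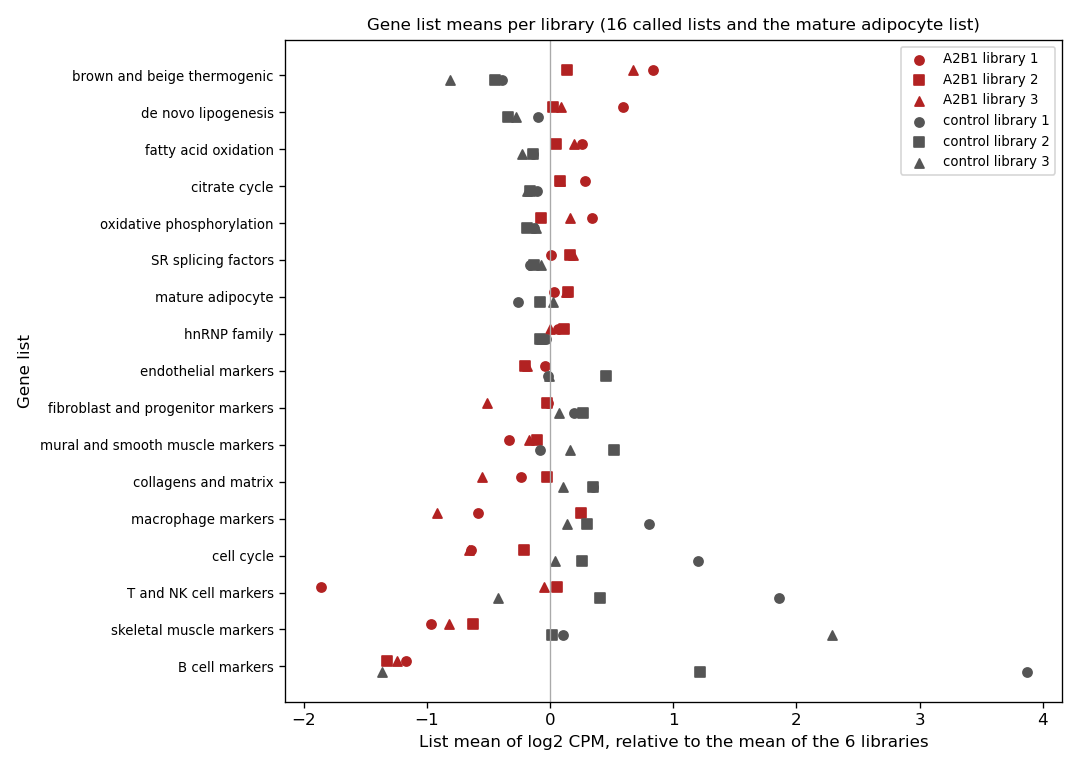
Mean log2 CPM of the members of each gene list in each library, as the difference from the mean of the 6 libraries (x axis, log2 units), for the 16 lists called by camera with a preset correlation and the mature adipocyte list, which was not called; red marks A2B1 and grey marks control libraries. The 3 A2B1 libraries lie above the controls for the thermogenic and mitochondrial lists, while control library 1 stands apart in the B cell list at 3.87 and control library 3 in the skeletal muscle list at 2.29.

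In total 16 of 40 lists were called by camera with the preset correlation, 7 higher and 9 lower. With an estimated correlation 0 were called, and fry in 1 direction called 0, with a lowest adjusted p of 0.0732. Fry's mixed test, which lets members move either way, called 23 of 40. It does not compare a list with other genes, and 4639 of all 19146 tested genes had an unadjusted p under 0.05. The 24 lists not called had adjusted p-values of 0.0721 to 0.954. With the preset correlation 6 of the 24 were called in at least 1 other scaling, filter or tool and 10 in at least 1 fit without 1 library, 11 in all. The unfolded protein and integrated stress response list (median 0.28, adjusted p = 0.0721) was called higher with no filter (0.0223), DESeq2 (0.0442), limma-voom (0.0464) and without A2B1 library 3 (0.000338). The lipolysis list (0.14, 0.0795) was called higher with no filter (0.0223), DESeq2 (0.0442), without A2B1 library 1 (0.0492) and without control library 2 (0.0444). Also not called were triglyceride synthesis (0.33, 0.0995), insulin signalling (0.08, 0.249) and p53 response (-0.20, 0.0873). Camera did call the p53 response list lower with the CPM filter (adjusted p = 0.0283) and without control library 2 (0.0476). Interferon response genes, which respond to viral nucleic acid, had a median of 0.08 (adjusted p = 0.659) but turned and were called lower without A2B1 library 2 (median -0.10, adjusted p = 0.0451). Antigen presentation genes had a median of -0.11 (adjusted p = 0.529), inflammatory cytokines and chemokines -0.36 (0.0995) and cytosolic ribosomal proteins -0.06 (0.485). Camera called the inflammatory list lower without A2B1 library 1 (adjusted p = 0.0218) and without A2B1 library 2 (0.0314). The ribosomal list was called lower without control library 2 (0.0138). Among markers of other tissues, the mammary and skin epithelial list had a median of 0.68 (adjusted p = 0.0846) and stood 1.5 above the mean in A2B1 library 1. It was called higher with DESeq2 (0.0198), library totals only (0.0466) and without A2B1 library 2 (median 0.28, adjusted p = 0.0183). The Schwann cell, erythrocyte, and neutrophil and mast cell lists had adjusted p-values of 0.685, 0.449 and 0.529. The immediate early and heat shock list (median 0.18, adjusted p = 0.84) was also highest in A2B1 library 1, by 0.95. Without that library it turned and was called lower (median -0.31, adjusted p = 0.0251). Circadian clock genes had a median of 0.10 (adjusted p = 0.297). The cholesterol synthesis list (adjusted p = 0.954) and the creatine and calcium cycling list (adjusted p = 0.721) had medians of 0.01 each, opposite in sign to camera's direction for both.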

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

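All but the fit of 2 against 2 libraries were planned before the data were examined. DESeq2's Wald test called 2919 genes (1332 higher, 1587 lower), of which 346 were among the 349, and an adjusted p under 0.1 called 1270 (472 higher, 798 lower). Higher calls numbered 147 with the CPM filter, 164 with limma-voom and 49 with library totals only. Leaving out 1 library gave 10 to 57 calls, 2 to 12 higher and 7 to 45 lower; these fits have fewer libraries. With 2 against 2 libraries 7 genes were called, 2 higher and 5 lower. The remaining settings (DESeq2 size factors, upper-quartile factors, no filter) called 295 to 340 genes. Where tool, scaling or filter moved a count, the cause was not tested. The log2 fold change of Hnrnpa2b1 was 0.45 with DESeq2 and 0.46 with limma-voom, both past the threshold, and 0.41 to 0.50 without any 1 library, never past it.

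Gene lists called numbered 15 to 20 under each scaling, filter, tool and set of libraries, but 0 with camera's estimated correlation and 0 with fry in 1 direction. With 2 against 2 libraries the T and NK cell list had a median of -0.25 and camera's direction reversed (adjusted p = 0.605). For the 16 called lists, the 6 fits without 1 library gave 96 values, 89 on the same side of the threshold and 7 no longer past it. All 78 named genes kept their sign in each fit that tested them. For the 46 that passed the threshold, non-overlapping groups made this nearly certain in advance. Depth limits genes with few counts, and 1146 genes had no DESeq2 adjusted p.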

Other observations

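The tests of other splits, adipocyte share, A2B1 library 1, lymph node tissue and control library 1 were chosen after their results had been seen; those of GC content, transcript length, imprinted genes and synaptic genes were not. The genes of the next 2 paragraphs were named after their values were seen.

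Secreted adipocyte factors moved in both directions. Sfrp5, a secreted Wnt inhibitor, fell from 131 ± 26.0 to 16.4 ± 1.51 CPM (SD, n = 3 each; log2 fold change -2.99, SE 0.17, adjusted p = 0.00841), and Apln, the peptide hormone apelin, fell from 25.6 ± 10.7 to 6.09 ± 1.14 (adjusted p = 0.0492, and up to 0.063 in the 3 of 7 other fits that lost the call). Nrg4, a factor secreted by brown fat, rose by 0.67 on the log2 scale (SE 0.09, adjusted p = 0.0334) and Vegfa, the vascular growth factor, by 0.62 (SE 0.09, adjusted p = 0.0335). The count of Nrg4 is uncertain, since its exons overlap Fbxo22 on the other strand. With Lep these were the 5 calls among 19 adipokines and batokines (2 higher, 3 lower; 4 higher and 7 lower adjusted over the list alone), a list that camera did not call (median -0.34, adjusted p = 0.0995) except on DESeq2's statistics, where it was lower (adjusted p = 0.00171). The chemokine Cxcl14 fell by 0.74 (SE 0.09, adjusted p = 0.0253). Of 16 tested triglyceride synthesis genes 12 were positive, and camera did not call the list (median 0.33, adjusted p = 0.0995). Only Dgat2, at a log2 fold change of -0.82 (SE 0.12, adjusted p = 0.0375), and Mogat2, at -2.31 (SE 0.35), passed over all genes and fell, whereas 5 were higher and 2 lower adjusted over the list alone. The lipid droplet protein Cidec fell by 0.62 (SE 0.11, adjusted p = 0.0497, and up to 0.0613 in the 3 of 7 other fits that lost the call) and Hilpda, an inhibitor of the lipase Pnpla2, by 1.47 (SE 0.22), unlike the droplet genes Cidea and Plin5, which rose. The insulin receptor substrate Irs1 rose from 77.1 ± 2.34 to 135 ± 9.86 CPM (SD, n = 3 each; adjusted p = 0.0235), and the adipocyte gene Adig rose by 0.78 (SE 0.12, adjusted p = 0.0402).

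Mest, an imprinted gene known to vary with fat pad expansion, fell from 516 ± 140 to 71.6 ± 8.38 CPM (SD, n = 3 each; log2 fold change -2.85, SE 0.22, adjusted p = 0.0144), and the imprinted Peg10 fell from 23.4 ± 6.29 to 5.41 ± 1.24. With Nap1l5 these prompted the hypothesis that imprinted genes were called more often than others. It was not borne out: without those 3 genes, 2 of 41 imprinted genes were called (Copg2 and Ampd3, 4.88% against 1.8% of other genes; odds ratio 2.8, two-sided Fisher's exact p = 0.169). With Mest, Peg10 and Nap1l5 included, DESeq2 called 3 imprinted genes higher and 6 lower, where it called 2919 of all 19146 tested genes. Limma-voom called 1 higher and 4 lower, of 515 calls in all. Copg2 and Mest share exons on opposite strands, and those of Ampd3 overlap Gm47282 and Rnf141, so the 3 counts are uncertain. A hypothesis that synaptic genes were lower as a group, prompted by Slc5a7, Grid1 and Unc79, was not borne out either. The 38 others, 27 negative and 11 positive, had a median log2 fold change of -0.29 and a camera p of 0.152. They had 0 calls in the main edgeR test, 1 higher and 2 lower in DESeq2, and unadjusted p under 0.05 for 4 lower and 3 higher.

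The mitochondrial gene mt-Atp6 had 1126 CPM in control library 3 and a similar value in control library 2, against 7208 to 9664 in the other 4 libraries, while mt-Atp8, whose sequence it overlaps, had 2775 to 4077 in all 6.

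The 349 calls were weighed against technical trends. Removing a smooth trend with GC content from each library left the median absolute log2 fold change of the called genes at 0.975 of its value, and 307 of 348 genes with a value remained called; for transcript length the share was 0.992, with 320 remaining. Neither trend accounts for the calls. The real grouping called 349 genes and the highest of the other splits 2 (1 of 10 splits reached 349), but 10 splits are too few for a share under 0.05. An effect of the delivered gene and any difference in animals, injection or dissection between the groups stay open, untested by this design.

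The higher thermogenic list could come from a larger share of adipocytes in the A2B1 libraries. Its median log2 fold change exceeded that of the mature adipocyte list by 0.702 (95% bootstrap interval over genes 0.0281 to 1.17). The interval reaches close to 0, and genes are not independent. The mature adipocyte list is also mixed, with 9 members higher and 5 lower at unadjusted p under 0.05. Over all genes 2 members were called higher, Adrb3 and Adig, and 2 lower, Lep and Cidec. The list mean was higher in every A2B1 library than in any control, but only just. Relative to the mean of all libraries, A2B1 library 1 lay at 0.033 and control library 3 at 0.0244 on the log2 scale. Macrophage, matrix, mural, fibroblast and endothelial lists were called lower with the preset correlation, which goes with a larger share. A larger share of adipocytes therefore stays open. A2B1 library 1, the library farthest out on the first principal component, did not carry the rise of the thermogenic list alone. Without that library the thermogenic median was 1.03 and the list stayed called with the preset correlation. The mammary and skin epithelial list ordered the A2B1 libraries as the thermogenic list did, 1 highest and 2 lowest, so a difference in the tissue taken is not excluded. In A2B1 library 2, however, it lay at -0.59 on the log2 scale, among the controls at -0.62 to -0.38, whereas the thermogenic list lay at 0.14, above controls at -0.39 or less. A different content of brown-like cells in the pads from the start and an effect of the delivered gene stay open, untested.

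The lower B cell list may reflect lymph node tissue in some control pads, since inguinal fat encloses a lymph node. The lowest control library lay at -0.116 relative to the A2B1 mean of the list on the log2 scale, and the lymph node stroma list ordered the 3 controls as the B cell list did, which is consistent with that reading. Control library 1 alone is not enough, because without it the median was still -1.78. Fcer2a, at 2651, 351 and 33 counts in controls 1 to 3, followed the same order, whereas Ighm, with 813 CPM in control library 3 against 337 to 419 CPM in A2B1 libraries, did not return to the A2B1 level there, so a difference in antibody-producing cells stays open. That point rests on Ighm alone. The list mean of control library 3 lay at -1.36, next to the A2B1 libraries at -1.17 to -1.32.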
